A study of Mus musculus with 2 samples.

How the data were processed

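Total RNA of whole back skin from mouse embryos at E18.5 was extracted with Trizol, amplified and labelled with Cy3 or Cy5 in a two-colour kit, per the labels' protocols, and hybridised to 2 Agilent whole mouse genome arrays. The deposited scanner files give spot brightness as intensity, made by Agilent Feature Extraction. The version is 10.1.1 per the labels and 10.7.1.1 per the file headers, and this disagreement was not settled. The files hold the median intensity of each spot and of its local background in both dyes, with no normalization, and Feature Extraction's processed intensity, which is background-subtracted, spatially detrended and dye-normalized per the file headers. The deposited log ratio is log10 of Cy5 over Cy3 processed signal. The deposited p-value belongs to Feature Extraction's error model for a single spot, not to samples. A deposited value table of both arrays holds log2 ratios by the authors. Set against each array's Agilent log2 ratio it had a slope of 1.00 on both arrays and r of 0.953 and 0.985, so its scale is log2 and its direction Cy5 over Cy3. Its columns have medians of 0.03 and -0.08, and how the authors normalized and centred it stays unknown.

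The sample with the label p120L/L, K5Cre+/+ formed the control group and the sample with the label p120Δ/Δ, K5Cre+/T the p120-deleted group, with 1 sample each. Both arrays lie on the same slide and scan, so neither was a batch to test. A mean spot signal was planned, and the median spot signal was used because the files hold no mean. Background was corrected with normexp at an offset of 50 and ratios were normalized within each array by loess (span 0.3, 4 iterations) in limma 3.58.1 under R 4.3.3, with 1639 control spots and 144 and 131 outlier spots on arrays 1 and 2 at weight 0. Control and outlier spots were then left out and the spots of a probe were averaged. Single channels were compared after loess and Aquantile normalization. The spike-in controls, per the file headers, gave an observed over expected log ratio slope of 0.934 and 0.928.

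The files carry accessions, which were matched without versions to a RefSeq gene table of assembly GRCm38.p6. Of 41174 probes, 23374 received a symbol and 17800 did not, and these stayed unnamed. The array's design refers to mm8, so no coordinates are printed. A gene was measured where a probe was well above background in at least 1 channel of both arrays, which left 13957 of 16535 genes, and 13491 were above background in both channels of both arrays. Its brightest probe stands for the gene, and named genes whose other probes differ by over 1.5-fold or in sign are given with both. A channel not well above background on both arrays was replaced by the lowest signal among probes above background, or its own if higher, which gives a fold as "at least". In the difference between the arrays the same was done for Cy5 that was dim on a single array. Some probes not well above background read higher than that lowest signal, so these bounds are approximate. They also remain open to dye bias.

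With 1 sample per group no test across samples was made and no p-value is given. The pooled SD between the arrays was 0.15 in log2. A gene counted as higher or lower in the shared ratio when both arrays passed the threshold in the same direction, and in the difference between the arrays when the difference passed it. The threshold was 2-fold for counts over all genes and 1.5-fold within lists. Each of 31 gene lists for cell types, tissues and pathways was fixed before the data were examined, without Ctnnd1. A list's median was placed among the medians of 10000 random lists of the same size matched on mean intensity in 20 bins, for the 30 lists with at least 5 measured genes. The shared ratio, its direction rule (r above 0.3) and the alternatives were also fixed before the data were examined, and no gene's level decided the direction. The difference between the arrays, listed beforehand only as an alternative, was taken up as a comparison of its own after the Cy3 channels were seen to be more alike than the Cy5 channels.

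The genes named are Ctnnd1, the 12 highest and 12 lowest genes of each comparison among those at least 1.5-fold apart, up to 4 members of each list with the widest ratio, and the measured sex-linked genes, all with a gene symbol rather than a clone or predicted name. Not all of them are printed. The same rule was applied to the difference, after the data had been seen.

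If both arrays shared a Cy3 RNA, its chance values would enter both ratios. In 100 simulations of unchanged RNAs against a shared Cy3 RNA, with the variation of the difference between the arrays, a median of 7 genes was 2-fold higher and 6 lower on both arrays, with highest values of 12 and 13, against 88 and 46 observed. Independent lists would share 1.66 and 0.47 genes. Over 13957 genes the correlation was 0.805 against a simulated 0.501, and the covariance 0.0826 against 0.0219. All simulated RNAs varied alike, which sets the simulated correlation near 0.5, and dye bias was left out. A Cy3 RNA that varies more would raise the correlation and the counts. With a single array per group the Cy3 RNA could not be split, and part or all of the excess over independent lists may come from it.

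The normalization was tested on simulated intensities for 30069 probes, with 50 probes at each fold change. At the 2-fold threshold on both arrays the normalization called 0 of 50 probes changed 1.5-fold, 4 of 50 changed 2-fold, 38 of 50 changed 4-fold and 46 of 50 changed 8-fold, with 0 false calls among the unchanged probes. The simulated noise was only that of replicate spots, with no dye bias and no variation between samples, so the absence of false calls says nothing of those. It recovered median log2 ratios of 0.46, 0.84, 1.70 and 2.58, so the offset shrinks ratios and changes near the threshold can be missed. Of 100 simulated unchanged lists of 20 genes, 7 fell outside the central 95%, and all 100 lists shifted by 0.3 lay above it. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the counts, lists and figures.

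The alternatives were no background subtraction, an offset of 16, Agilent's processed ratios, median centring, stricter and no filters on dim probes, the median over probes, either array alone, a spot p-value under 0.01, the authors' value table, the other orientation, thresholds of 1.5-fold and 3-fold, and unmatched random lists. Single channels, added after the data were seen, were also tried.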

Results

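Gene expression was measured in the back skin of mouse embryos at E18.5, late in gestation, on a mixed BL6/CD1 background, with 2 two-colour Agilent whole mouse genome arrays on the same slide, read in the same scan. The labels give array 1 to a control without Cre (p120L/L, K5Cre+/+) and array 2 to skin in which p120-catenin was deleted (p120Δ/Δ, K5Cre+/T). K5Cre is a recombinase under a keratin 5 promoter, which is active in basal keratinocytes and the hair follicle. p120-catenin, the product of Ctnnd1, binds classical cadherins at adherens junctions and modulates Rho GTPases, and the study's title names Rho-dependent and secreted signals as its subject. Each group holds 1 sample, so there is no replicate and no test across samples, and the number of arrays limits the precision. The median spot brightness was 113.5 and 289 intensity units in Cy3 and Cy5 on array 1, and 111 and 295 on array 2. Of 43379 non-control spots, 76.4% and 71.3% were well above background in Cy3 on arrays 1 and 2, and 74.1% and 73.5% in Cy5. No spot was saturated. The 10 spots of the same probe differed by a median SD of 0.060 and 0.071 in log2 ratio on arrays 1 and 2, over 211 probes printed that often.

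The labels leave the dyes unsettled. They call the other channel of each array wild-type skin but give it the same dye as the array's own RNA. That dye is Cy3 on array 1 and Cy5 on array 2. The genotype written for that channel, p120L/L, K5+/T, carries the same K5 notation as the deleted sample, so what it held is unclear. The log2(Cy5/Cy3) ratios of both arrays correlated at r = 0.78 (Spearman's rho 0.68) across 28580 probes, which are not independent replicates. Over the 13957 measured genes r was 0.805. Unchanged RNAs simulated against a shared Cy3 RNA gave a median r of 0.501 and at most 0.535. All simulated RNAs varied alike, which by itself sets r near 0.5, and a Cy3 RNA that varies more would raise it. A positive r, or its excess over the simulated value, therefore does not show a shared change. The mean ratio of both arrays, called the shared ratio here, is reported as Cy5 over Cy3, with the SD between the arrays. It would be p120-deleted over control if both arrays held control RNA in Cy3 and deleted RNA in Cy5. That needs deleted skin in the channel of array 1 that the labels call wild-type, and the labels do not settle it. If instead each array's own RNA had its labelled dye and the other dye held the same wild-type RNA, the sum of both ratios would be deleted over control. The shared ratio would then be that log2 ratio divided by 2. In that reading the wild-type RNA enters both ratios with opposite signs, which by itself pulls r below 0, against the 0.78 seen. A dye bias would raise r, so the sign of r does not settle it. The Cy3 channels of both arrays were more alike (SD of the log2 difference 0.126, 24 probes at least 2-fold apart) than the Cy5 channels (SD 0.226, 110 probes). If Cy3 held a common wild-type RNA on both arrays and Cy5 each array's own sample, the genotypes would instead be compared by the difference between the arrays. This reading needs the control of array 1 in Cy5, against its Cy3 label. Both comparisons are described. Whether the dyes were swapped between the arrays is not settled by the labels. A dye bias of single probes would add to the shared ratio and cancel in the difference.

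Ctnnd1 itself was lower in Cy5 on both arrays. Its brighter probe, A_52_P184435, had a shared log2 ratio of -0.59 ± 0.018 (SD between the arrays), 1.5-fold lower, with -0.60 on array 1 and -0.57 on array 2. Its dimmer probe gave -0.095. The difference between the arrays was 0.026 at the brighter probe, within the replicate-spot SD of 0.085 for such a difference. Where these probes lie relative to the deleted exons is not given in the sources used here, so the values check neither the labels nor the dye direction.

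The shared ratio addresses which genes differ between p120-deleted and control skin if both arrays hold deleted RNA in Cy5 and control RNA in Cy3. Fat, striated muscle, hair and pigment genes were higher in Cy5, and genes of the outer epidermis were lower, as were Msln, Krt7, Upk3b, Krt18 and Krt19. The adipocyte list had a median shared ratio of 1.02 and the skeletal muscle list of 0.96. The cornified envelope list had a median of -0.77. Of 13957 measured genes, 88 were at least 2-fold higher and 46 at least 2-fold lower on both arrays, and none was 2-fold higher on either array and 2-fold lower on the other.

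Of 24 adipocyte genes, 14 were at least 1.5-fold higher on both arrays and none was lower. Plin1, which coats lipid droplets, had a shared ratio of 2.68 ± 0.22, or 6.42-fold. The adipokine Adipoq stood at 2.67 ± 0.51 and the lipid droplet gene Cidec at 2.54 ± 0.65. Gpd1, a glycerol phosphate enzyme, read 2.51 ± 0.47, while its other probe read 0.66. Of 35 skeletal muscle genes, 23 were higher and none was lower, and 34 lay above 0. Myh8, the perinatal myosin heavy chain, read 2.48 ± 0.23 and its other probe 1.24. The myosin binding protein Mybpc2 read 2.42 ± 0.25. The fast troponin Tnnc2 read 2.03 ± 0.54. Myh1 read 2.21 ± 0.076 at its brighter probe and 0.13 at its other probe. Of 31 actomyosin and SRF targets, some of which are muscle genes, 9 were higher, with a median of 0.22. Skeletal actin Acta1 read 1.70 ± 0.33, and smooth muscle actin Acta2 read 1.28 ± 0.12 at its brightest probe but 0.44 and 0.62 at its other probes.

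Hair and pigment genes were higher too. Among 22 hair shaft keratins and associated proteins, 9 were higher and 2 lower, with a median of 0.23. Krt71 read 2.97 ± 0.21, Krt25 read 2.76 ± 0.26 and Krt27 read 2.66 ± 0.21, all keratins of the inner root sheath, and the hair cortex keratin Krt35 read 2.26 ± 0.14. Of 8 melanocyte genes, 4 were higher and all lay above 0, with a median of 0.57. The melanin enzyme genes Tyrp1 and Dct stood at 1.14 ± 0.10 and 0.73 ± 0.061, and the melanosome gene Pmel at 0.67 ± 0.078. Camp, the neutrophil antimicrobial peptide cathelicidin, read 2.47 ± 0.035, while only 1 of 30 leukocyte markers, Camp itself, was higher on both arrays. Clca1 read 2.94 ± 1.41, with 3.94 on array 1 and 1.94 on array 2.

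The lowest shared ratio belonged to Msln. This gene, which encodes the surface protein mesothelin, stood at -4.11 ± 0.13, 17.3-fold lower. Krt7 followed at -3.28 ± 0.17, the urothelial and mesothelial gene Upk3b at -3.06 ± 0.058, Krt18 at -2.82 ± 0.032 and Krt19 at -2.18 ± 0.79. The myelin and raft protein genes Mal and Pllp read -2.04 ± 0.10 and -1.98 ± 0.013. The other probe of Mal read -2.33 and that of Pllp -1.05. The protease inhibitor gene Serpinb11 read -1.98 ± 0.05, and the lens crystallin gene Cryaa read -1.90 ± 0.036 at its brighter probe and -0.58 at its other probe. S100a7a and Crisp1 were not well above background in Cy5 on either array. They were lower there by approximate bounds of at least 4.27-fold and at least 3.73-fold.

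Genes of the differentiated epidermis were lower as groups, in the same comparison in which muscle and fat markers were higher. Of 25 measured cornified envelope genes, which build the outermost layer, 13 were at least 1.5-fold lower on both arrays and none was higher. Sprr1a read -2.09 ± 0.15 and Lce1c read -1.34 ± 0.47. Sprr3 read -1.80 ± 0.49 but was not well above background in Cy5 on array 2. Lce1g read -1.23 ± 0.46, and its other probe -0.36. Of 23 spinous and granular layer genes, 4 were lower, and the median was -0.35. Ivl (involucrin) read -1.06 ± 0.35 and Flg2 read -1.06 ± 0.42. Of 21 stress and wound genes of keratinocytes, 8 were lower and none higher, with a median of -0.25. Krt6a, a keratin of wounded epidermis, read -1.68 ± 0.45, the defensin Defb14 read -1.61 ± 0.17 and the interleukin 36 gene Il1f9 read -1.37 ± 0.27. The epidermal lipid barrier list had a median of -0.27, with none of 26 genes lower on both arrays and 2 higher. These were Elovl3 at 1.61 ± 0.25 and Scd1 at 1.18 ± 0.42, both fatty acid enzymes of sebaceous glands and fat. The basal keratinocyte list had a median of -0.15, with none of 13 genes 1.5-fold apart on both arrays. Krt5 read 0.41 ± 0.0083 and Lamc2 read -0.48 ± 0.04.

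Among junction genes, 3 of 22 tight and gap junction genes were lower on both arrays, with a list median of -0.13. Cldn1 (claudin 1) read -1.51 ± 0.11 at its brighter probe and -0.33 at its other probe, Cldn23 read -1.01 ± 0.17 and the connexin gene Gjb6 read -0.92 ± 0.30. The desmosome list had a median of -0.11, with 1 of 12 genes lower on both arrays, Ppl (periplakin) at -1.03 ± 0.35. That median came almost wholly from array 2, with -0.0027 on array 1 and -0.21 on array 2. None of the 19 genes of the p120 and adherens junction list passed 1.5-fold on both arrays, and the list's median of -0.042 lay within the central 95% of random lists. Cdh1 (E-cadherin) read -0.62 ± 0.74.

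None of 47 Rho GTPase pathway genes and none of 25 NF-kB components and targets was 1.5-fold apart on both arrays. The medians of these lists were -0.043 and -0.057, and both lay within the central 95% of random lists. These are transcript levels, and the activity of Rho GTPases or NF-kB was not measured. The guanine exchange factor gene Vav3 had the widest Rho ratio, -0.57 ± 0.018, and the chemokine gene Cxcl10 the widest in the NF-kB list, 0.45 ± 0.34. Of 53 secreted growth factor genes, 2 were higher and 1 lower. Their median of 0.16 lay above the central 95% of random lists, as it did under 7 of the 8 other processings applied to both arrays. Btc, which encodes the EGF family ligand betacellulin, read -1.70 ± 0.58, and Gdf15 read 0.80 ± 0.15. Of 44 chemokine and cytokine genes, 1 was higher and 2 were lower. Ccl19, a chemokine of lymphoid stroma, read 1.55 ± 0.23, Il18 read -0.88 ± 0.15 and Cxcl14 read -0.77 ± 0.044. The chemokine and cytokine median of 0.054 lay within the central 95% of random lists, and above it under 3 of the 8 other processings applied to both arrays.

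Of the 30 lists with at least 5 measured genes, 9 had a median above and 9 below the central 95% of 10000 random lists matched on intensity. Lists of independent genes would put 1.5 outside. Genes of the same list can vary together and some lists share genes, so 1.5 is too low a yardstick. The desmosome and basal keratinocyte medians each fell inside that range under 2 of the 8 other processings, and the leukocyte median under all 8. This describes these arrays and is no test over animals. Loess sets most genes near 0. With median centring in its place the median of all genes lay at 0.32 and 291 genes were at least 2-fold higher and 34 lower, against 88 and 46 with loess. Relative to that 0.32, the muscle, adipocyte and melanocyte lists stayed above 0 and the cornified, spinous, stress, lipid, desmosome and tight and gap junction lists below 0, while the basal keratinocyte list (0.012), the hair shaft list (0.015) and the leukocyte list (-0.039) were close to 0. Against random lists of like intensity under median centring, the hair shaft median still lay above the central 95% (percentile 99.7) and the basal keratinocyte median below it (1.63). The leukocyte (67.6), desmosome (5.98) and tight and gap junction (3.88) medians lay inside.

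**Figure D1:**
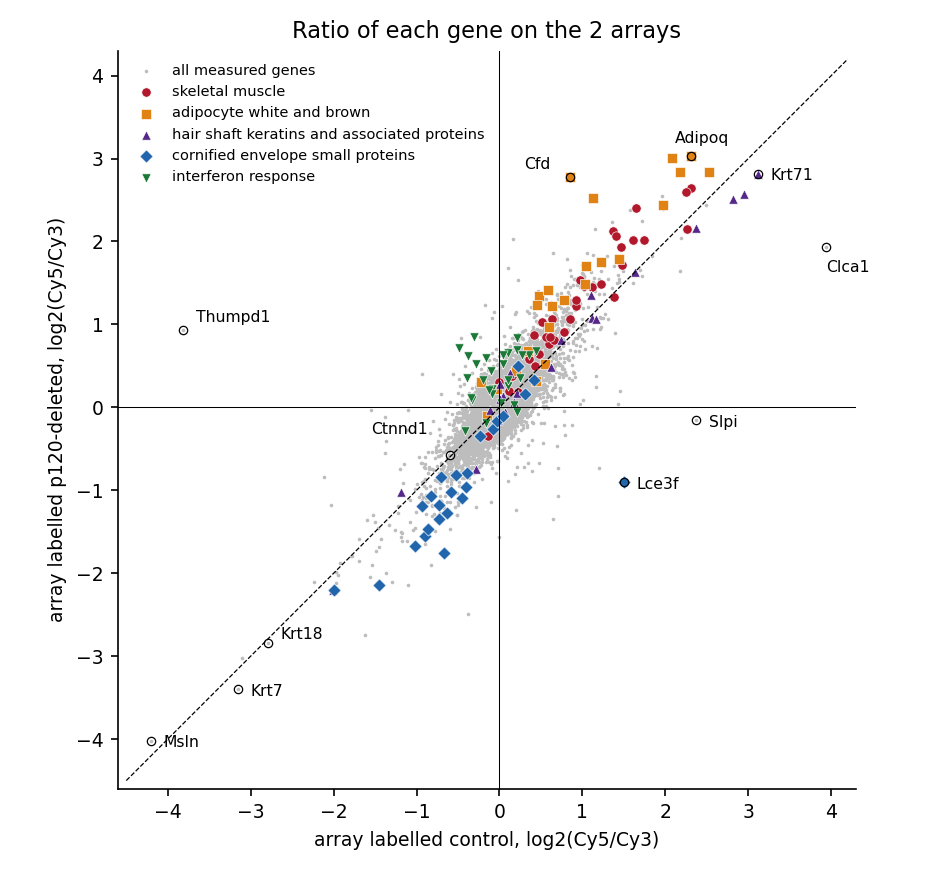
Log2(Cy5/Cy3) of each measured gene on the array labelled control (x axis) and the array labelled p120-deleted (y axis), with the members of 5 gene lists in colour, named genes circled and equal values on the dashed line. Muscle and adipocyte genes lie mostly at the upper right and cornified envelope genes at the lower left of these loess-normalized ratios; with median centring the median over all genes lies at 0.32, and list medians move by -0.094 to 0.67.

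The arrays were then set against each other. This comparison asks how the array labelled p120-deleted differed from the array labelled control, each relative to its own Cy3 channel. Adipocyte genes and genes induced by interferon were higher on the array labelled p120-deleted, with list medians of 0.53 and 0.42 in log2. Cornified envelope genes were lower there, with a median of -0.40, and so were the p120 and adherens junction list and the desmosome list, each at -0.16. Of 13957 genes, 21 were at least 2-fold higher on that array and 24 at least 2-fold lower. Replicate spots of the same probe varied by a median SD of 0.085 in this difference. No array was repeated, so the variation between samples of a genotype is unknown. Ratios were also wider on array 2 (SD of the log2 ratio 0.285) than on array 1 (0.241) and were not scaled between the arrays. A list away from 0 in the shared ratio, as the adipocyte, muscle and cornified lists were, can thereby move further the same way in the difference.

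Of 24 adipocyte genes, 10 were at least 1.5-fold higher on the array labelled p120-deleted and none was lower. Cfd (adipsin) differed by 1.92 in log2, or 3.78-fold, the adipokine gene Retn by 1.40 at its brighter probe, Cidec by 0.92 and the brown fat gene Cidea by 0.87. The perilipin gene Plin5 differed by 1.32. Of 35 skeletal muscle genes, 3 were higher, with a median of 0.27. Myl1 and Tnnc2 each differed by 0.76 and Tnni2 by 0.67, mostly through lower Cy3 on that array (-0.52, -0.55 and -0.49). In Cy5 alone they differed by 0.23, 0.21 and 0.18, and none passed 1.5-fold, with a list median of 0.19. The sarcoplasmic reticulum gene Dhrs7c differed by 1.41. The tissue kallikrein genes Klk1b26 and Klk1b16, near-identical relatives that are uncertain for that reason, differed by 1.86 and 1.57.

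Of 29 interferon response genes, 8 were at least 1.5-fold higher and none was lower. The ubiquitin-like gene Isg15 differed by 1.21, Oasl2 by 1.16, Ifit1 by 0.99 and Usp18 by 0.81. Leukocyte markers had a median of 0.29, with 3 of 30 higher. These were the complement genes C1qb at 0.76 and C1qc at 0.64, which macrophages express, and the neutrophil granule gene Ngp at 0.70. Of 44 chemokine and cytokine genes, 4 were higher and none lower, with a median of 0.075. Ccl24 differed by 1.07, Ccl27a by 0.84, Ccl9 by 0.70 and Cxcl9 by 0.59, the last by 0.46 in Cy5 alone. The mast cell list had a median of 0.20, with 1 of 10 genes higher, the tryptase gene Tpsb2 at 0.66. Interferon and leukocyte genes had negative medians, -0.086 and -0.061, on the array labelled control and positive medians, 0.35 and 0.20, on the array labelled p120-deleted.

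Of 25 cornified envelope genes, 9 were at least 1.5-fold lower on the array labelled p120-deleted and none was higher, while adipocyte and leukocyte markers were higher on that array. In Cy5 alone, 5 of these 9 were 1.5-fold lower, and the list median was -0.34. Lce3f differed by -2.41 and Sprr1b by -1.09. Sprr3, not well above background in Cy5 there, was lower in Cy5 by an approximate bound of at least 1.75-fold. Of 23 spinous and granular genes, 3 were lower, with a median of -0.20. These were the fused S100 genes Rptn at -1.99 and Flg2 at -0.59, and the suprabasal keratin Krt10 at -0.91. The stress and wound list, with a median of -0.25, moved both ways. In it 4 of 21 genes were lower, among them the protease inhibitor gene Slpi at -2.53 and Serpinb3a at -0.87, and 2 were higher, the calprotectin genes S100a8 at 1.19 and S100a9 at 1.17.

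Cdh1, printed as 10 spots, was 2.06-fold lower on the array labelled p120-deleted (-1.04, SD of the spots 0.10), and was the only gene of 19 in the p120 and adherens junction list to differ by 1.5-fold. Jup (plakoglobin) read -0.29 and Ctnnd2, a relative of p120-catenin, -0.36. Of 12 desmosome genes, 1 was lower, the desmocollin gene Dsc1 at -0.67, and Ppl read -0.49. Betacellulin (Btc) differed by -0.81 and was the only gene of 53 secreted growth factors past 1.5-fold, and Col7a1, the collagen of anchoring fibrils, differed by -0.60 (-0.53 in Cy5 alone) and was the only such gene of 31 in the integrin and basement membrane list. None of 47 Rho GTPase genes and none of 25 NF-kB genes differed by 1.5-fold. Their medians of -0.028 and 0.096 lay within the central 95% of random lists, though the NF-kB median lay above it under 3 of the 8 other processings applied to both arrays.

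Smaller shifts ran downwards in several lists with no gene past 1.5-fold. The proliferation list, of 36 genes, had a median of -0.13, hair follicle morphogenesis and Wnt, Shh and Bmp signalling -0.12 over 45 genes, immediate early and heat shock genes -0.10 over 30, and tight and gap junctions -0.078 over 22. Ccnd1 (cyclin D1) read -0.49 and Bmp7 -0.57. Of the other genes with the widest differences, Clca1 read -2.0, Krt12 -1.93, Arg1 (arginase 1) -1.77, the transcription factor gene Foxf2 -1.38, though its Cy3 on array 2 was not well above background, and the myeloid receptor gene Cd300lf -1.43. Lgals4 read -2.12 at its brighter probe and -0.89 at its other probe, with shared ratios of -1.44 and -0.65. Pop4 read -1.55.

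In all, 6 lists had a median difference above and 9 below the central 95% of random lists, out of 30. Here too, genes of the same list can vary together and some lists share genes. The comparison was also taken up after the data were seen, so this count is a description only. With Agilent's own processed ratios 125 genes were at least 2-fold apart, against 45 here. The chemokine and cytokine median fell within the central 95% of random lists under 5 of the 8 other processings and the tight and gap junction median under 6.

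**Figure D2:**
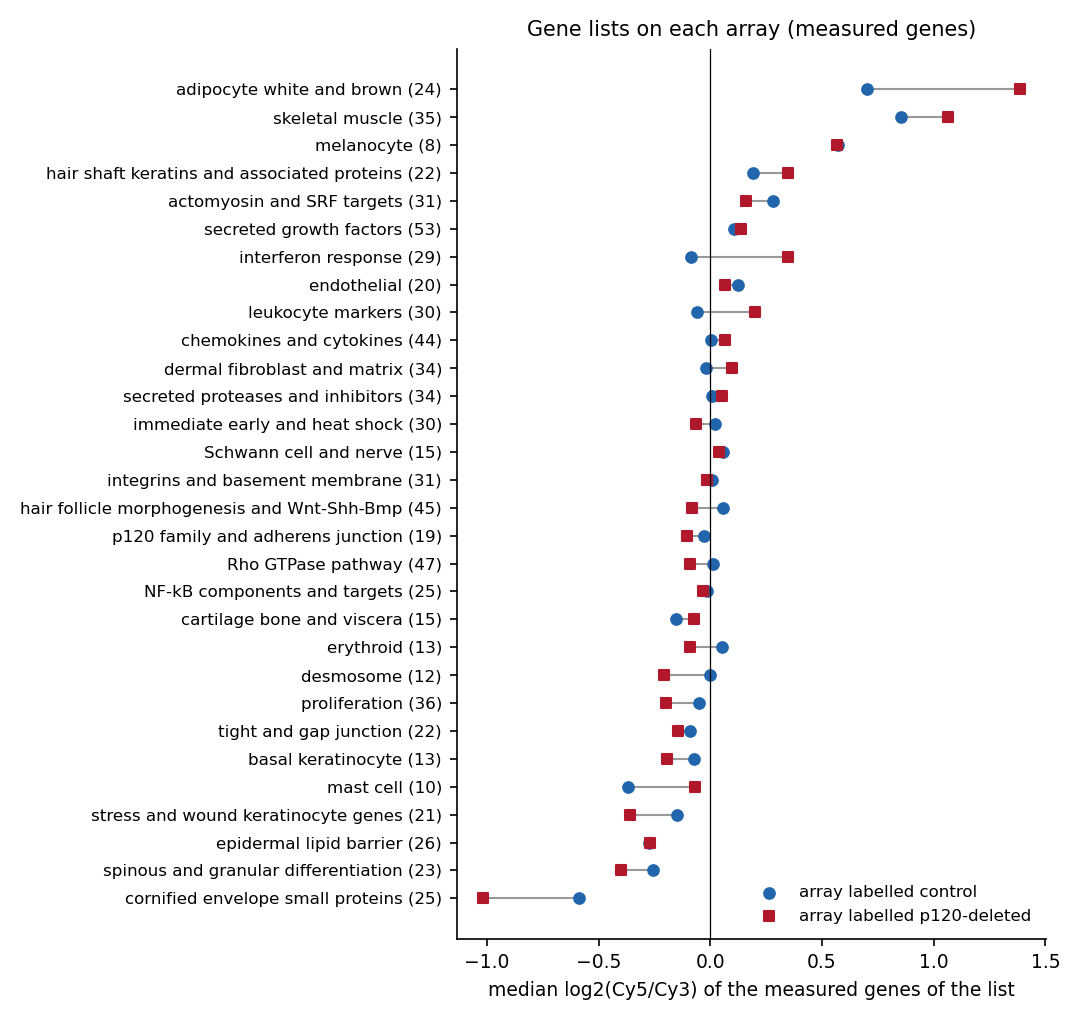
Median log2(Cy5/Cy3) of the measured genes of each list (number in brackets) on the array labelled control (blue circles) and on the array labelled p120-deleted (red squares), joined by a line, with loess normalization. The adipocyte list lies at 0.70 and 1.39, the cornified envelope list at -0.59 and -1.02, and the interferon list on opposite sides of 0; with median centring in place of loess the median shared ratio over all genes lies at 0.32.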

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

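Chosen after their results were seen were the tests of dye bias, of less epidermis and of more muscle for the muscle genes, and the tests of epidermis and leukocytes for the difference between the arrays.

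Of the measured genes, 6 were at least 1.5-fold higher in Cy5 on either array and at least 1.5-fold lower on the other. More genes, Slpi and Isg15 among them, changed sign with a smaller ratio on at least 1 array. These differences were not tested, since each group has 1 sample. Thumpd1 read -3.81 on the array labelled control and 0.93 on the array labelled p120-deleted, a difference of 4.75 from a single spot on each array. Lce3f, a late cornified envelope gene, read 1.5 and -0.91, a difference of -2.41. Rptn (repetin) read 0.65 and -1.34, a difference of -1.99. Krt12 read 1.20 and -0.73, a difference of -1.93, and Arg1 read 0.70 and -1.07, a difference of -1.77. Prcp read 0.70 and -0.73, a difference of -1.43, and its other probe differed by -0.80. The Y-linked gene Eif2s3y, short of 1.5-fold on the array labelled control, read -0.47 and 0.84, a difference of 1.30. It was not well above background in Cy5 of the first or Cy3 of the second of these arrays. Only an approximate bound is therefore given, at least 2.32-fold higher Cy5 on the second. The Y-linked genes Ddx3y and Kdm5d, added after their values were seen and well above background only in Cy5 of the array labelled p120-deleted, read -0.23 and 0.51, and 0.040 and 0.26. Xist read 0.43 and 0.33 and the Y-linked Zfy1 read 0.21 and -0.043, with Cy3 not well above background on the second array. The labels do not give the sex of the embryos, so a difference in sex make-up between the samples stays open.

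Skeletal muscle genes and adipocyte genes were higher in Cy5 on both arrays. A bias of single probes towards a dye would not be expected to follow the tissue a gene marks. The muscle median lay at percentile 100 among random lists of like intensity, so intensity alone does not account for it. This percentile otherwise restates the pattern, so dye bias was not tested independently. A smaller share of epidermis in the Cy5 RNA would raise the markers of every other cell type alike, but 69 fibroblast, endothelial and Schwann cell genes had a median of 0.052, against 0.96 for muscle and 1.02 for adipocytes, which argues against it as the whole cause. More muscle or fat tissue in the Cy5 RNA was not tested independently either, since the 97.1% of muscle genes above 0 restates the pattern. It stays open, as do dye bias, dissection and genotype.

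The lowest shared ratios belonged to Msln, Krt7, Upk3b, Krt18 and Krt19, which mesothelium expresses. A candidate explanation was mesothelium in the Cy3 RNA, from tissue beneath the skin. A list of 12 other mesothelial genes was written after these genes were seen but before its own values. Its 8 measured members did not fall as a set, with a median of 0.071, and Wt1 at 0.028, Aldh1a2 at 0.53 and Cldn15 at 0.44. Whether other cells of whole skin supply these transcripts was not examined, so mesothelium is not excluded. Dye bias cannot be told apart, because none of these genes has another measured probe. Of the 12 lowest genes, Mal, Pllp and Cryaa have 3 other probes, and 100% of these lay below 0, which says nothing of the others. Other epithelia that use these keratins were not tested, and genotype stays open.

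Cornified envelope genes were lower and interferon response genes higher on the array labelled p120-deleted. A smaller share of epidermis in that sample would lower basal keratinocyte genes as well. Their median difference was -0.10, nearer to 0 than the cornified median of -0.40. Its bootstrap standard error of 0.040 is over the genes of the list, which are not replicates, and says nothing of the spread between samples. A smaller share of epidermis as part of the cause stays open. More leukocytes may account for the interferon genes, and this cannot be told apart. Leukocyte markers had a median difference of 0.29 with a standard error of 0.059, again over genes. That is below the interferon median of 0.42 but not far enough below it to exclude them. Genotype, litter and dissection stay open, as each array holds 1 sample.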

How the results depend on the processing

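No paired analysis was possible because each group has 1 sample. Without background subtraction, with an offset of 16, with either filter on dim probes and with a spot p-value under 0.01, the counts stayed within 1.5 times of those reported and no called gene or list changed sign. Agilent's processed ratios gave 250 genes at least 2-fold apart on both arrays (163 higher, 87 lower) in place of 134, and 125 (65, 60) in the difference between the arrays in place of 45. The authors' value table gave 253 (166, 87) and 126 (66, 60). Of the 134 genes, 129 and 131 were among them, in the same direction. Median centring gave 325 genes, 291 of them higher. It moved Ctnnd1 to -0.34 and, with the median over all genes at 0.32, moved these list medians above 0: basal keratinocyte 0.33, desmosome 0.16, lipid barrier 0.20, mast cell 0.23, proliferation 0.34, spinous and granular 0.10, stress and wound 0.16, tight and gap junction 0.20. Of lists inside the central 95% it moved Rho GTPase to 0.34, NF-kB to 0.23, p120 and adherens junction to 0.40 and hair follicle morphogenesis to 0.35. Relative to all genes, basal keratinocytes (0.012), proliferation (0.020), Rho GTPase (0.020), p120 and adherens junction (0.081) and hair follicle morphogenesis (0.033) stayed above 0. Against random lists of like intensity, though, the proliferation (percentile 0.07) and basal keratinocyte (1.63) medians still lay below the central 95%. The other medians of this group lay inside it (6.85, 35.6 and 76.9). The median over a gene's probes moved Ctnnd1 to -0.34, through its dimmer probe. Array 2 alone gave 330 genes (216, 114), and array 1 alone turned the medians of interferon response (-0.086) and leukocyte markers (-0.061). The other orientation, the difference between the arrays divided by 2, left 4 genes (1, 3) and put Ctnnd1 at 0.013, endothelial genes at -0.031, hair shaft genes at -0.032 and mast cell genes at 0.099. It turned Krt71 (-0.15), Clca1 (-0.998), Krt25 (-0.19), Krt27 (-0.15), Camp (-0.025), Krt35 (-0.10), Msln (0.092), Upk3b (0.041), S100a7a (0.064), Cryaa (0.025), Bglap (0.00195), Afp (0.11), Col1a2 (-0.036) and Myh1 (-0.054). A threshold of 1.5-fold gave 472 genes (303, 169) and 193 (114, 79) in the difference, and 3-fold gave 41 (25, 16) and 10 (3, 7). In Cy5 alone, chosen after seeing the data, 67 genes (34 higher on array 2, 33 lower) were 2-fold apart, and in Cy3 alone 11 (4, 7). The cause was not tested, except where the setting itself sets the count. Signal over background limits dim genes: S100a7a and Crisp1 have only a bound in the shared ratio, and Eif2s3y and Sprr3 in the difference between the arrays. The shared ratios of Sprr3 and Afp are given without a bound though Cy5 was dim on a single array. The same holds for the difference of Foxf2, with dim Cy3 on array 2.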

Other observations

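Mast cell genes had a median shared ratio of -0.23 with none of 10 at least 1.5-fold apart on both arrays. The mast cell proteases Cpa3 and Cma1 read -0.49 ± 0.33 and -0.53 ± 0.19. Proliferation genes had a median of -0.12 over 36 genes, interferon response genes 0.12 over 29, endothelial genes 0.11 over 20 and leukocyte markers 0.094 over 30, all outside the central 95% of random lists. The interferon and leukocyte medians were below 0 on array 1 (-0.086 and -0.061) and above it on array 2 (0.35 and 0.20). On arrays 1 and 2 the proliferation median was -0.052 and -0.20, and the mast cell median -0.37 and -0.070. The leukocyte median was inside it under all 8 other processings that were applied to both arrays, and the mast cell and endothelial medians under 1 each. Relative to 0.32, the median over all genes under median centring, the interferon and endothelial medians were 0.092 and 0.19, the proliferation median 0.020, the mast cell median -0.092 and the leukocyte median -0.039. Against random lists of like intensity these lay at percentiles 99.99, 97.56, 0.07, 4.8 and 67.6, in the same order.

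Of 45 genes of hair follicle morphogenesis and Wnt, Shh and Bmp signalling, 2 were at least 1.5-fold higher on both arrays and 2 lower, with a median shared ratio of -0.004. The secreted Wnt antagonist genes went both ways, with Sfrp4 at 1.00 ± 0.19, Wif1 at -0.83 ± 0.07 and Dkk4 at -0.66 ± 0.065. Dermal fibroblast and matrix genes had a median of 0.048 over 34 genes, and Col1a2, a chain of type I collagen, was the single gene past 1.5-fold, at 0.87 ± 0.05. Among 15 genes of cartilage, bone and viscera, 2 were lower on both arrays, the osteocalcin gene Bglap at -1.79 on both arrays and the fetal liver gene Afp at -1.41 ± 0.16 (not well above background in Cy5 on array 1), while the list's median of -0.060 lay within the central 95%. The heat shock genes Hspa1b and Hspa1a read -0.69 ± 0.35 and -0.54 ± 0.23, with a median of 0.037 for 30 immediate early and heat shock genes.

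The medians of the remaining lists lay within the central 95% of random lists in both comparisons. In the shared ratio they were 0.034 for 15 Schwann cell and nerve genes, -0.065 for 13 erythroid genes, 0.016 for 31 integrin and basement membrane genes and 0.040 for 34 secreted proteases and inhibitors. The difference between the arrays was 0.058, -0.053, -0.034 and 0.038 in the same order, and 0.025 for dermal fibroblast and matrix genes, but the erythroid median fell below the central 95% under 5 of the 8 other processings. In the difference the hair shaft median was -0.064, the melanocyte median 0.098, the actomyosin median 0.042 and the lipid barrier median -0.047. The endothelial median was -0.061, the basal keratinocyte median -0.10, the secreted growth factor median 0.012 and the cartilage, bone and viscera median -0.041, all within the central 95%. The hair shaft median fell below that range under 2 of the 8 other processings.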
